A study of Mus musculus with 144 samples.

How the data were processed

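The data were expression values of single cells sorted from the retina of Iba1-EGFP mice given PBS or ripasudil, with 48 cells in each of 3 groups and 16 cells of each group on each of 3 plates. Per the labels' protocols, each cell was lysed, its cDNA was made and amplified in the same tube, and libraries were made by tagmentation with the Nextera XT kit. No molecular identifiers were named, so reads are not independent molecules and all intervals cover counting error only. The labels gave the group, plate, well and age but no animal.

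The authors deposited FPKM values (expression scaled to gene length and to the reads assigned in that cell) for 55364 genes and all cells, with a gene length in bases for each gene. Per the submitters' processing notes, the tools were Trim Galore 0.4.4, Trimmomatic 0.36, cutadapt 1.16, STAR 2.7.2b and featureCounts 1.6.1, on GRCm38.p6 (mm10). The order and role of the trimming tools, the settings and the use of strand were not given in the sources used here, so reads of overlapping genes on opposite strands were treated as not separable. Of the gene identifiers, 55104 were in GENCODE release M21 and 54784 of these had the same coordinates there. Genes of the mitochondrial chromosome were not analysed here. A copy of mitochondrial DNA on chromosome 1 carries 7 genes, which were left out in an alternative.

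FPKM multiplied by gene length summed to the same constant in each cell, so the values are shares of assigned reads. In each cell the most frequent positive value of FPKM multiplied by gene length was taken as 1 read. This gave the assigned reads per cell, 30204 to 4668733. A median of 53.1% of the values above 0 (37.8 to 70.5% over cells) were whole reads within 0.01 read. How many of the others fell on 0.5, 0.33 or 0.25 of a read was not counted. The others were not whole reads, as can happen when a read is shared between genes. For that reason no count model was used. No columns of other samples were present. No pair of cells held the same library, the highest correlation between cells being 0.75.

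Groups, comparisons, gene lists, markers, the rule for named genes and the first set of alternatives were chosen before the data were examined. Cells with at least 1000 genes at an FPKM of 1 or more were kept, 140 in all, and 4 were left out. A gene counted as detected in a cell at an FPKM of 1 or more. Levels were means of log2(FPKM + 1) over cells, and a difference was the difference of such means, pooled and within each plate. These differences understate changes of genes that many cells lack. Genes at an FPKM of 1 or more in at least 25% of the kept cells of any group, 4806 in all, entered the comparison of all genes. Shares of cells carry exact Clopper-Pearson 95% intervals. As each group was 1 sample, no p-value, standard error or number of changed genes was computed.

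There were 18 gene lists, 1 of them the title genes, and members at an FPKM of 1 or more in at least 10% of the kept cells were used. A list was described by the median difference of its members, the number lower, its plate medians and the percentile of its median among 10000 random lists of the same size, drawn in 20 bins of mean expression. Lists share some members, and 1 list and some single genes are not reported here. The percentiles describe these libraries and are not p-values.

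Genes named singly were, for each dose against PBS, the 12 with the largest positive and the 12 with the largest negative difference among those with the same sign on all 3 plates. Gene models, clones, pseudogenes and mitochondrially encoded genes were left out. The 3 title genes and the 2 members of each list with the largest differences were added. For the high against the low dose there were 6 in each direction. Other list members are named as examples and were picked after their values were seen.

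Cells were clustered on the 2000 most variable genes with 15 principal components, 10 neighbours and Leiden resolution 0.5, and a cluster was named from 19 marker lists. No doublet caller was run, since each library was a sorted cell. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 were used. For the agreement of the doses, 100 sets of groups without an effect were drawn from the cells.

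The calculations were tested on simulated data for the high dose against PBS, with 4806 genes of which 50 at each fold were altered. A 4-fold lower expression was estimated at a median of -0.72 in the difference of mean log2 values and -1.28 in the log2 ratio of mean FPKM, and 48 of 50 genes had the right sign in the former. When detection was lowered for all genes, unaltered genes had a median of -0.61, and of -0.14 after adjustment for detected genes. In that setting only 22 of 50 genes made 4 times higher had a positive difference of mean log2 values. Assigned reads of 12 simulated cells were recovered to within 0.0%. These cells were built from the reads already inferred, so 1 read stayed the most frequent value. The recovery therefore does not show that the depths of the real cells are right.

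Alternatives were other filters on cells, detection thresholds of above 0 and of 10, a pseudocount of 0.1, rescaling to the same sum per cell or by the median of ratios, the ratio of mean FPKM, equal weights for plates, leaving out each plate, other filters on genes and a Leiden resolution of 1.0. A common range of detected genes was set from 1716 to 4957, between the highest 10th and the lowest 90th percentile of the groups, and held 31 PBS, 26 low-dose and 29 high-dose cells. Alternatives chosen after seeing the data were thinning each cell to 300000 reads, adjustment for the log2 number of detected genes with 1 slope per gene fitted within group and plate, subtraction of the median of all genes, leaving out the chromosome 1 copy of mitochondrial DNA, and leaving out cells that were rich in rod markers, rich in S100a8 and S100a9 or unlike all others.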

Results

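RNA of single retinal microglia was sequenced from Iba1-EGFP mice, in which microglia and other Iba1-positive cells carry a green fluorescent protein. The cells were sorted by flow cytometry from mice given vehicle (PBS) or ripasudil, an inhibitor of the kinases ROCK1 and ROCK2. The series concerns GPR84, a receptor for medium-chain fatty acids, and its link to the cytokines TNF and IL-1α after damage to the optic nerve. The labels did not state whether the eyes of these mice had been injured. Each group held 48 cells, 16 on each of 3 plates. PBS cells came from mice of 10 to 14 weeks, cells of the low dose (1 mg/kg) from mice of 14 weeks and cells of the high dose (10 mg/kg) from mice of 12 weeks, so dose and age were not separated. On every plate each group took its own block of wells, so dose and well position were not separated either.

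The labels named no animal, so each group was 1 sample, no difference had a replicate check, and no test across cells was made. The values below describe these cells; intervals cover counting error only, and the spread between animals is unknown. Reads assigned to genes numbered 30204 to 4668733 per cell, with a median of 1614850. Of the cells, 140 had at least 1000 genes at an FPKM of 1 or more and entered the comparisons, namely 46 PBS, 47 low-dose and 47 high-dose cells.

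PBS cells held more detected genes than dosed cells. The median over all cells of a group was 2923.5 genes in PBS cells, 2406 at the low dose and 2263 at the high dose, over a range of 876 to 9077. By plate, the medians were 2562.5, 3889.5 and 2173 in PBS cells, 1588, 3061.5 and 2421.5 at the low dose, and 1827.5, 2495.5 and 1887 at the high dose. With every cell thinned to 300000 reads, genes with a read numbered 2759, 4030.5 and 2960 in PBS cells and 2403, 2534.5 and 2158 at the high dose, on plates 1, 2 and 3. At the low dose they numbered 1987, 2669 and 2591.5. The thinning left out 5 PBS, 1 low-dose and 4 high-dose cells with fewer reads.

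**Figure D1:**
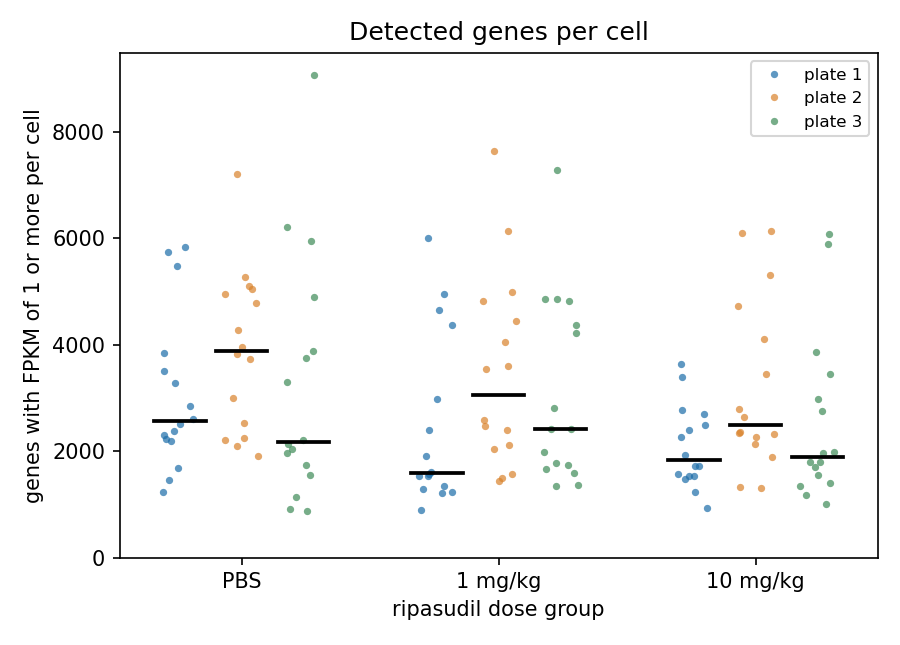
Number of genes with an FPKM of 1 or more in each cell (vertical axis), by dose group and plate; points are cells and bars are medians of a plate. The high-dose medians (1827.5, 2495.5 and 1887) lie below the PBS medians (2562.5, 3889.5 and 2173) on each plate.

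The sorted cells carried microglial transcripts in every group. Csf1r, the receptor of colony-stimulating factor 1, was detected in 100% of the 140 cells, Tmem119 in 88.6% and the purinergic receptor P2ry12 in 77.9%. Clustering gave 3 clusters, each microglia-like by the markers chosen beforehand, and together they held 100% of the cells. Markers of other cell types were rarer. At least 3 of the 10 rod photoreceptor markers were found in 24 cells, 3 of the 8 neutrophil markers in 26, of which Csf3r alone was in 50, and 3 border macrophage markers in 16. For monocytes the number was 4, for Müller glia 2, and 1 each for dendritic, endothelial, pericyte and erythroid markers. No cell held 3 markers of T or NK cells, B cells, cones, astrocytes, ganglion cells, bipolar cells, amacrine cells, pigment epithelium or oligodendrocytes, although single members of these lists such as Ighm (96 cells) and Gngt2 (113 cells) were common.

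Rod transcripts were most abundant in high-dose cells. Cells with at least 3 rod markers numbered 6 of the PBS, 7 of the low-dose and 11 of the high-dose cells. A summed FPKM of the markers of 100 or more was reached by 1 PBS, 5 low-dose and 10 high-dose cells. That PBS cell held 1 marker, so none of the 6 PBS cells with 3 markers reached this sum. The mean summed FPKM of the 10 markers was 12.99 in PBS cells, 264 at the low dose and 892 at the high dose. A few cells carried these means, as the 3 highest cells held 73.5%, 94.0% and 71.0% of the sums, and the median cells stood at 0.73, 0.57 and 1.04.

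The first comparison asked whether ripasudil at 1 mg/kg altered the genes named in the series title. Tnf and Il1a were found in fewer low-dose than PBS cells, while Gpr84 was found in a similar share. Tnf was detected in 25 of 47 low-dose cells (53.2%, exact Clopper-Pearson 95% interval 38.1 to 67.9) against 35 of 46 PBS cells (76.1%, 61.2 to 87.4). Il1a, which encodes interleukin 1 alpha, was detected in 30 cells (63.8%, 48.5 to 77.3) against 40 (87.0%, 73.7 to 95.1). Gpr84 was detected in 36 cells of each group, 76.6% (62.0 to 87.7) of low-dose and 78.3% (63.6 to 89.1) of PBS cells. By plate the shares differed by -34.6, -12.5 and -20.5 points for Tnf, -27.5, -25.0 and -17.0 for Il1a, and -2.08, -12.5 and 8.93 for Gpr84, which differed by 4.09 points without plate 2 and by -7.16 without plate 3. The pooled differences of -22.9 points for Tnf and -23.1 for Il1a were -6.58 and -7.33 in cells with at least 2000 detected genes, -14.7 and -10.5 at any FPKM above 0, and -11.6 and -11.7 at an FPKM of 10 or more. The share with Gpr84 differed by 8.65, -6.34 and -7.54 points in these settings. Fewer reads suffice for an FPKM of 1 in a library with fewer reads, which can raise the share of cells counted. Such libraries were more common among PBS cells, of which 5 had fewer than 300000 reads against 1 low-dose cell.

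Mean log2(FPKM + 1) of Tnf was 3.16 ± 3.74 (SD over 47 cells) at the low dose and 4.13 ± 3.76 (46 cells) in PBS cells, a difference of -0.97, with -0.97, -0.28 and -1.72 on the 3 plates. For Il1a the means were 4.0 ± 4.05 and 4.73 ± 3.79, a difference of -0.73, with -1.33, -0.40 and -0.47 by plate. Gpr84 gave 4.34 ± 3.77 and 4.83 ± 3.54, a difference of -0.50, with -0.37, -1.24 and 0.01 by plate. Single plates weighed on these values, which were -0.59 for Tnf without plate 3, -0.44 for Il1a without plate 1 and, for Gpr84, -0.089 without plate 2 and -0.77 without plate 3. Mean FPKM was 214 and 211 for Gpr84, 191 and 251 for Tnf and 310 and 349 for Il1a in low-dose and PBS cells. After adjustment for the number of detected genes per cell, the mean difference of the 3 genes was 0.039 in place of -0.73, and among cells within a common range of detected genes it was 1.12, the opposite direction. That range did not equalise detected genes, whose medians within it were 2615 in PBS, 2896 in low-dose and 2393 in high-dose cells. Without cells holding 3 or more rod markers the mean difference was -0.42.

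Gpr84 (ENSMUSG00000063234) lies on chromosome 15 at 103308235 to 103310612, Tnf (ENSMUSG00000024401) on chromosome 17 at 35199381 to 35202007, and Il1a (ENSMUSG00000027399) on chromosome 2 at 129299610 to 129309972, all on the minus strand of GRCm38. Gpr84 overlaps Gm49482 and Il1a overlaps Gm14023, so reads in the overlaps are of uncertain origin.

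Among the gene lists other than the title genes, antigen presentation, proliferation and actin cytoskeleton genes stood lowest at the low dose. Antigen presentation genes had a median difference of -0.71, with 12 of 15 measured members lower, among them H2-DMa (-1.51), the immunoproteasome subunit Psmb8 (-1.36), Cd74 (-1.33) and B2m (-1.13). Only 0.165% of 10000 random lists of the same size and expression had a lower median. Proliferation genes had a median of -0.57 with 17 of 18 members lower (percentile 0.03), for example Tubb5 (-1.12), Ccnb2 (-1.04) and the survivin gene Birc5 (-1.0). Actin cytoskeleton and SRF target genes had a median of -0.51 with 20 of 24 lower (percentile 1.28), including the tropomyosin Tpm4 (-1.46) and Coro1a (-1.44). Within plates the antigen presentation medians were -0.66, -0.30 and -0.44, those of proliferation -0.65, -0.39 and -0.77, and those of actin genes -0.82, -0.32 and -0.60. Adjusted for detected genes per cell, the medians were -0.23 for antigen presentation, -0.32 for proliferation and -0.20 for actin genes, and in the common range they were -0.17, -0.067 and 0.14.

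Interferon response genes had a median of -0.43 at the low dose (16 of 22 lower, percentile 1.48), led by Ifitm3 (-1.97) and Oas1a (-1.41). Proinflammatory cytokines and chemokines had -0.44 (11 of 15 lower, percentile 4.97), led by Ccl2, a monocyte chemoattractant (-2.44), and a median of -0.18 without plate 3. Of all 4806 genes, 64.7% were lower at the low dose, a share beside which the counts of lower members should be read. Their median was -0.18. Relative to it these lists stood at -0.25 and -0.26, and antigen presentation, proliferation and actin genes at -0.53, -0.40 and -0.33. In the log2 ratio of mean FPKM, the direction of the interferon (0.59), cytokine (0.23) and antigen presentation (0.19) lists was the opposite. Interferon and cytokine genes had medians of -0.14 and -0.062 after adjustment for detected genes, and of 0.24 and 0.38 in the common range.

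The other lists lay closer to the median of all genes at the low dose. Oxidative phosphorylation had a median of -0.33 (15 of 22 lower), immediate early genes -0.31 (15 of 22, with -1.13, -0.17 and 0.38 by plate), homeostatic microglia -0.23 (14 of 24), phagocytosis and lysosome -0.18 (15 of 27) and TGF-beta signalling -0.18 (5 of 8). Medians were -0.14 for the cytosolic ribosome (13 of 24 lower), -0.067 for glycolysis (10 of 16), -0.063 for complement (5 of 9), -0.062 for lipid handling (11 of 18), -0.059 for NF-kB (11 of 17) and -0.0047 for disease-associated microglia (12 of 23). Relative to all genes, the ribosome, glycolysis, complement, lipid, NF-kB and disease-associated lists were above 0, from 0.034 to 0.17. After adjustment for detected genes all of these lists except oxidative phosphorylation (-0.041) were above 0, from 0.018 for TGF-beta signalling to 0.27 for disease-associated microglia. In the common range all of them were above 0, from 0.24 for TGF-beta signalling to 1.10 for immediate early genes.

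Single genes lowest at the low dose, with the same sign on all plates, were the chloride channel protein Clic1 (-2.53), Ccl2 (-2.44), the complex I subunit Ndufa7 (-2.19), and thioredoxin, Txn1 (-2.07). Psmd3 (-2.05), Nme1 (-2.03), Snx3 (-2.03), Dek (-1.99), Ifitm3 (-1.97), Tmco1 (-1.89) and Rps6ka1 (-1.86) followed. Clic1 was detected in 78.7% of low-dose and 100% of PBS cells. Ifitm3 had the opposite sign in the log2 ratio of mean FPKM (0.40). Psmd3, Nme1, Dek and Rps6ka1 overlap other gene models, as do the list members Tpm4, Coro1a, H2-DMa, Psmb8 and Cd74, and Ccnb2 has a processed copy, so their values are uncertain.

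The metallothionein Mt1 was the gene with the greatest positive difference at the low dose, with means of 4.87 ± 3.92 and 2.71 ± 3.26, a difference of 2.15, and 1.997, 1.68 and 2.94 on the plates. It was detected in 74.5% of low-dose and 54.3% of PBS cells. Srsf9 (1.23), Mrpl16 (1.15), Mtch1 (1.13) and Commd9 (1.06) were also higher. The values of the G protein subunit Gnas (1.22), Dhx32 (1.09) and Cops6 (1.07) are uncertain, since these genes overlap Gnasas1, Bccip and Mcm7. Rpl7a (1.26), Rps13 (1.24) and Aldoa (1.07) have processed copies elsewhere in the genome and Mir704 (1.06) lies within Pdia4, so their values are uncertain.

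The next comparison put the high dose of 10 mg/kg against PBS. Gpr84, Tnf and Il1a were lower in high-dose cells in mean level, and Gpr84 and Il1a also in the share of cells at an FPKM of 1 or more on each plate. Gpr84 was detected in 26 of 47 high-dose cells (55.3%, 40.1 to 69.8) against 78.3% of PBS cells, Tnf in 31 (66.0%, 50.7 to 79.1) against 76.1%, and Il1a in 32 (68.1%, 52.9 to 80.9) against 87.0%. At an FPKM of 10 or more, Gpr84 was found in 14 high-dose and 25 PBS cells, Tnf in 11 and 20, and Il1a in 17 and 24. At any FPKM above 0 the shares differed by only -2.08 points for Gpr84 and -4.16 for Il1a, and that of Tnf had the opposite direction (2.31). By plate the shares at an FPKM of 1 or more differed by -8.75, -31.2 and -28.6 points for Gpr84, -27.5, -18.8 and -10.7 for Il1a, and -27.9, 0.0 and -1.79 for Tnf, whose pooled difference of -10.1 points was -1.46 without plate 1 and -15.3 without plate 2.

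Mean log2(FPKM + 1) of Gpr84 was 3.18 ± 3.53 at the high dose and 4.83 ± 3.54 in PBS cells, a difference of -1.66, with -0.42, -2.16 and -2.43 by plate. Tnf gave 2.74 ± 3.0 and 4.13 ± 3.76, a difference of -1.39, with -1.98, -0.71 and -1.55 by plate. Il1a gave 3.43 ± 3.39 and 4.73 ± 3.79, a difference of -1.29, with -2.50, -0.43 and -1.01 by plate and -0.73 without plate 1. The ratio of mean FPKM, high dose to PBS, was 0.717 for Gpr84, 0.331 for Tnf and 0.479 for Il1a; on plate 1 the Gpr84 ratio was 2.7. Adjusted for detected genes per cell, the mean difference of the 3 genes was -0.16 in place of -1.45, and among cells within a common range of detected genes it was -0.86.

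**Figure D2:**
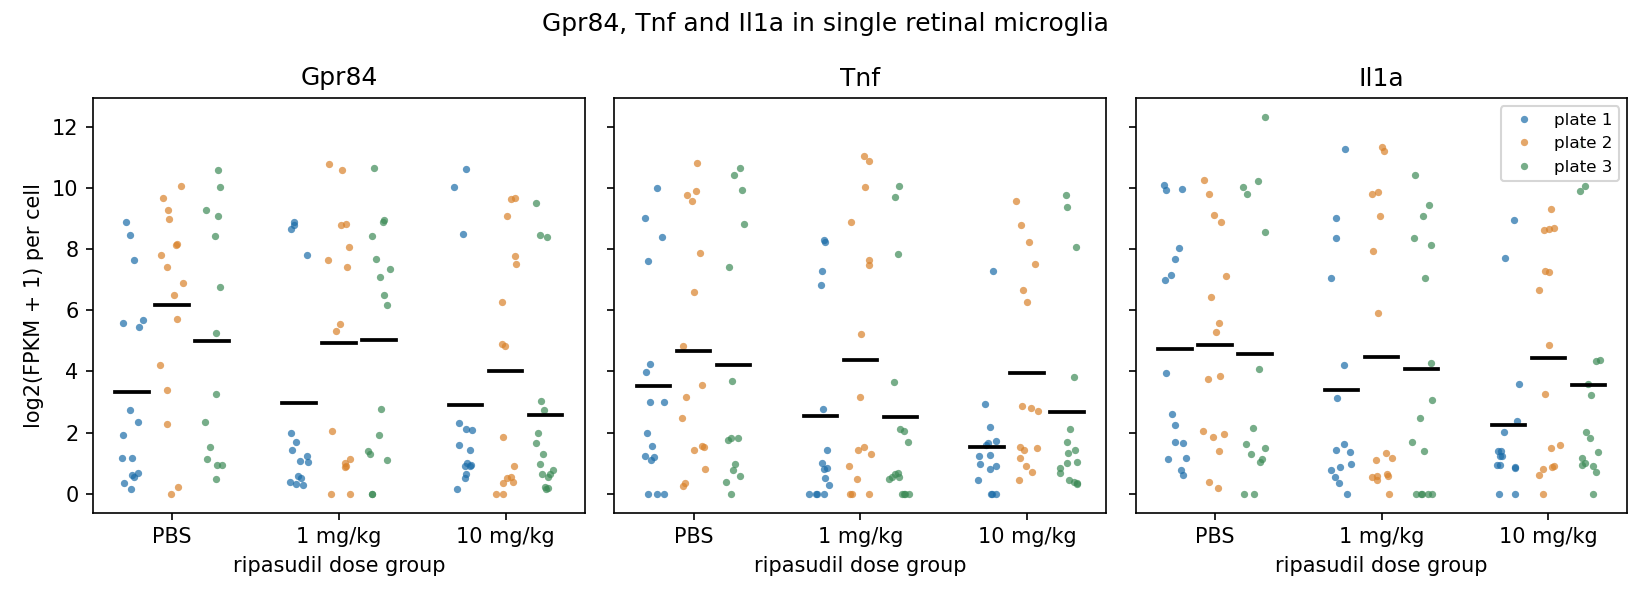
Log2(FPKM + 1) of Gpr84, Tnf and Il1a in each cell (vertical axis), by dose group and plate; points are cells and bars are means of a plate. High-dose means lie below PBS means on each plate for all 3 genes, with pooled differences of -1.66, -1.39 and -1.29, while the cells of every group spread over most of the range.

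Apart from the title genes, immediate early, actin cytoskeleton and proliferation genes had the lowest medians at the high dose. Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, had a median difference of -1.26 with 21 of 22 members lower and 0.0% of random lists below it. Btg2 (-2.07), Junb (-2.0), Klf6 (-1.66) and Egr1 (-1.63) were among them, and within plates the medians were -1.77, -0.56 and -1.12. The list did not stand lowest after adjustment for detected genes per cell, at -0.19 (-0.52, -0.0004 and 0.065 by plate), and was at -0.51 in the common range, where actin genes were at -0.55 and proliferation genes at -0.78. Actin cytoskeleton and SRF target genes had a median of -1.02 with 23 of 24 lower (percentile 0.02), for example Tpm4 (-1.75), thymosin beta 10 (Tmsb10, -1.69) and zyxin (Zyx, -1.31), and plate medians of -1.32, -0.74 and -0.92. All 18 proliferation genes were lower, with a median of -1.0 (percentile 0.0) and plate medians of -1.31, -0.78 and -0.99. They included the microtubule regulator Stmn1 (-2.41), Hmgb2 (-2.07), Tubb5 (-2.02) and the replication clamp Pcna (-1.58).

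Transcripts of the kinases inhibited by ripasudil were sparse. Rock1 was detected in 10.6% of high-dose, 19.1% of low-dose and 30.4% of PBS cells, with differences from PBS of -0.52 and -0.48. Rock2 was detected in 10.6%, 6.38% and 23.9%, with differences of -0.30 and -0.56. At the high dose the share with Rock2 differed by 0.83, -25.0 and -15.2 points by plate. The ratio of mean FPKM, high dose to PBS, was 0.20, 1.14 and 2.08 by plate for Rock2 and 2.40, 0.16 and 0.22 for Rock1. In that ratio the plates did not agree in direction. In mean log2(FPKM + 1) the high-dose differences from PBS were below 0 on each plate. They were -0.46, -0.66 and -0.40 for Rock1 and -0.065, -0.55 and -0.28 for Rock2.

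Oxidative phosphorylation genes had a median of -0.86 at the high dose (20 of 22 lower, percentile 3.10), among them Atp5g3 (-1.72). In the common range of detected genes that median was -0.30. Antigen presentation had -0.75 (12 of 15 lower, percentile 5.76), led by H2-K1 (-1.80). Its median was 0.17, the opposite direction, in cells with at least 2000 detected genes, and -0.057 in the log2 ratio of mean FPKM. NF-kB pathway genes had -0.50 (14 of 17 lower, percentile 6.50), led by Nfkbia (-2.01) and Nfkbiz (-1.78). Cytokines and chemokines had a median of -0.57 (13 of 15 lower, percentile 19.9), with Ccl2 at -1.72, Ccl3 at -1.14 and Ccl4 at -1.02, and a median of -0.32 without plate 3. TGF-beta signalling had -0.56 (8 of 8 lower, percentile 7.85), homeostatic microglia -0.54 (22 of 24, percentile 30.3), complement -0.48 (5 of 9, percentile 43.9) and phagocytosis and lysosome -0.44 (21 of 27, percentile 50.8). Of the homeostatic genes, P2ry12, which overlaps Med12l, was at -1.05 and Tmem119 at -0.29, while Csf1r (0.46) and Cst3 (0.68) were higher.

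Interferon response (-0.35, 15 of 22 lower), glycolysis (-0.33, 13 of 16), cytosolic ribosome (-0.29, 14 of 24), disease-associated microglia (-0.23, 17 of 23) and lipid handling (-0.19, 13 of 18) had medians above that of all genes at the high dose. Of the 4806 genes, 81.4% were lower at the high dose and their median difference was -0.43. Relative to it, immediate early genes stood at -0.83, actin genes at -0.60, proliferation genes at -0.58, oxidative phosphorylation at -0.43, and antigen presentation at -0.32. Interferon response, glycolysis, ribosome, disease-associated and lipid genes stood at 0.076, 0.092, 0.13, 0.20 and 0.23, above 0. After adjustment for detected genes per cell, the median of all genes was -0.053, that of proliferation genes -0.75, of actin genes -0.26, of oxidative phosphorylation -0.25, of immediate early genes -0.19, of NF-kB genes -0.18, of antigen presentation and TGF-beta signalling -0.15 each, and of cytokines -0.036. Medians were above 0 after that adjustment for complement (0.39), homeostatic microglia (0.23), ribosome (0.17), lipid handling (0.15), disease-associated microglia (0.15), phagocytosis (0.15), interferon (0.11) and glycolysis (0.090).

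**Figure D3:**
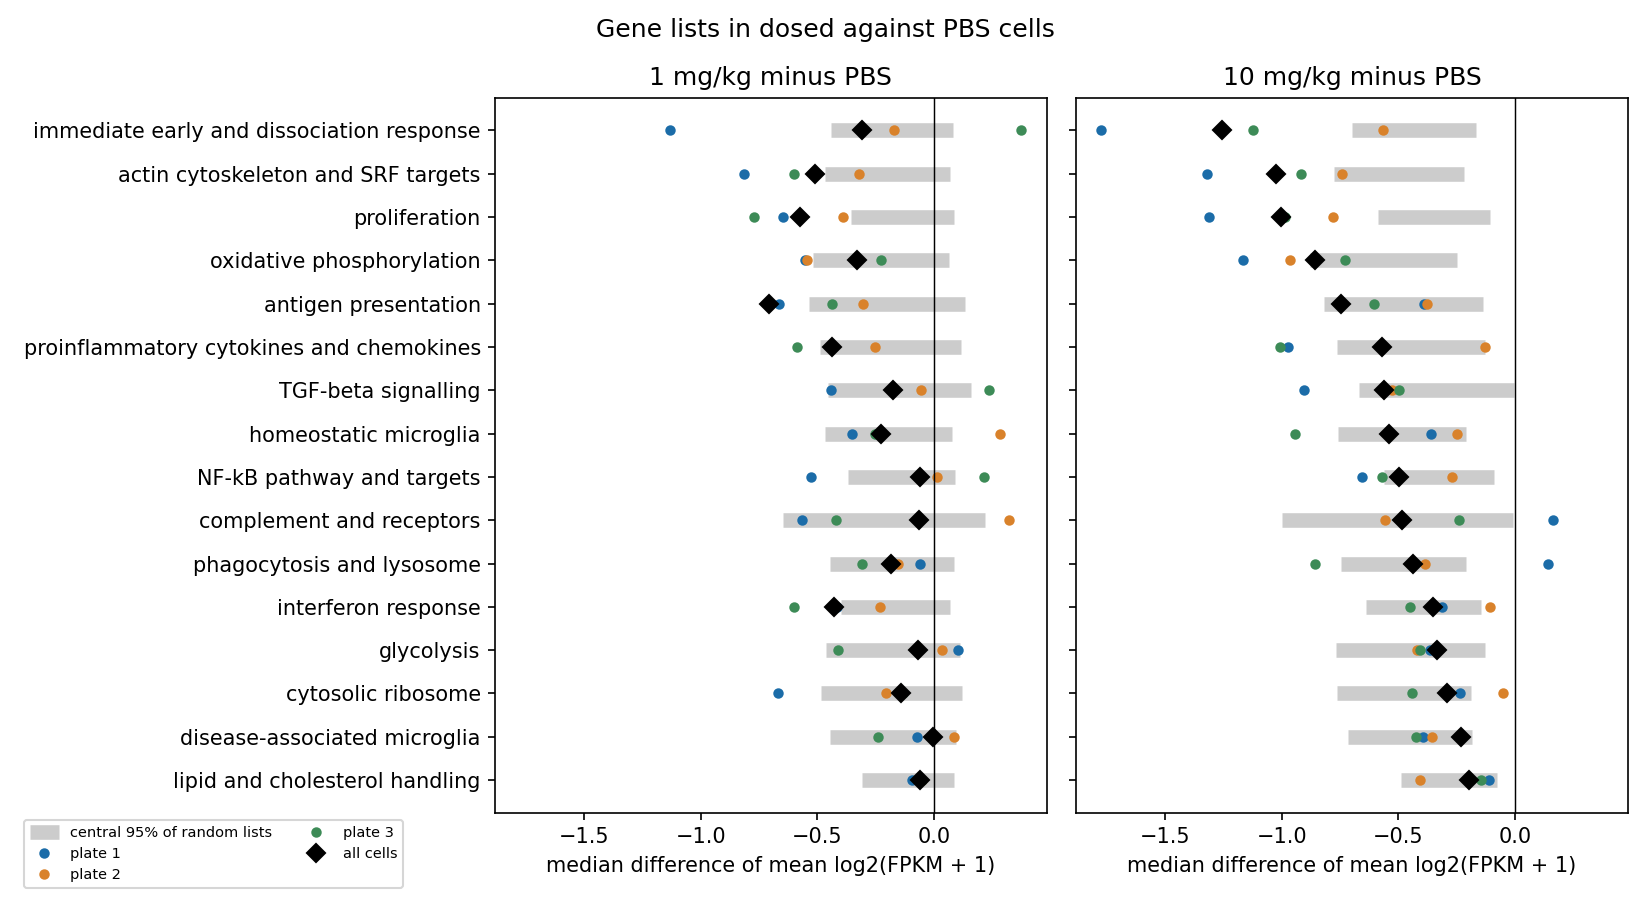
Median over list members of the difference in mean log2(FPKM + 1) from PBS cells (horizontal axis) for the gene lists described here, at 1 and 10 mg/kg; diamonds are all cells, circles are plates and grey bars span the central 95% of random lists. At 10 mg/kg the immediate early (-1.26), actin (-1.02) and proliferation (-1.0) lists lie below the grey bars, values that were -0.19, -0.26 and -0.75 after adjustment for detected genes.

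Single genes lowest at the high dose included the proteasome subunit Psmc5 (-2.66), Txn1 (-2.45), Stmn1 (-2.41), Clic1 (-2.40), Tmco1 (-2.22), Jpt1 (-2.16) and the RNA-binding protein Hnrnpa1 (-2.09). Csf2ra, a subunit of the receptor for granulocyte-macrophage colony-stimulating factor, was at -2.08, as was Herpud1, and Btg2, Hmgb2 and the cathepsin Ctsh were at -2.07. Clic1 was detected in 74.5% of high-dose against 100% of PBS cells, and Tmco1 in 27.7% against 65.2%. In the log2 ratio of mean FPKM Txn1 had the opposite sign (0.13).

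The rod genes Gnat1 (1.32) and Prph2 (1.18), which encode rod transducin alpha and a photoreceptor disc protein, had the greatest positive differences at the high dose. Without cells holding 3 or more rod markers, Prph2 was at -0.065, while the sign of Gnat1 did not change. Both genes are among the markers that defined those cells, so the exclusion itself lowers them. Arhgdib was higher by 1.08 and Pde6h by 0.90, but these genes overlap on opposite strands, and reads of one cannot be told from the other. Cyb5r1 (0.98), Poldip2 (0.73), the chemokine Ccl5 (0.71) and the cystatin Cst3 (0.68) were also higher. Cetn3 (0.72) and Dnajc7 (0.71) overlap other gene models, as do Stmn1 and Tpm4 among the lower genes, and are uncertain. Rpl18 (0.87), which also overlaps Sphk2, Rpl13 (0.85) and, among the lower genes, Pcna have processed copies, which makes their values uncertain.

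The last contrast set the high dose against the low dose. Gpr84 was detected in 26 against 36 cells and was lower at the high dose, with a difference in mean log2 value of -1.16, with -0.057, -0.92 and -2.44 by plate. At any FPKM above 0 its share was higher at the high dose, by 4.26 points. Tnf was detected in more high-dose cells (66.0% against 53.2%) but had a lower mean (-0.41, with -1.02, -0.43 and 0.17 by plate), and at an FPKM of 10 or more it was found in 11 against 15 cells. Il1a was detected in 68.1% against 63.8%, with a mean difference of -0.57. As a list, the 3 genes had a median difference of -0.57 between the doses (percentile 25.3 among random lists). The mean differences were -0.50 for Gpr84 without plate 3, -0.13 for Tnf without plate 1 and -0.71 without plate 3, and -0.29 for Il1a without plate 1, and the share with Gpr84 differed by -12.9 points without plate 3.

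Immediate early genes were lower at the high than at the low dose, with a median of -0.84 and 20 of 22 members lower (percentile 0.0), for example Btg2 (-1.57) and Zfp36 (-1.50), and plate medians of -0.35, -0.61 and -1.51. Oxidative phosphorylation (-0.62, 17 of 22 lower, percentile 1.99) and proliferation genes (-0.54, 16 of 18, percentile 0.11) were also low, including Sdhb (-1.51), Stmn1 (-1.44) and Pcna (-1.41). NF-kB pathway genes had a median of -0.33 with 15 of 17 lower (percentile 8.75), led by Nfkbiz (-1.72) and the adhesion molecule Icam1 (-1.17). Interferon response genes had the highest median of the 18 gene lists, 0.15, with 15 of 22 members higher at the high dose (percentile 99.97; 0.041, 0.26 and -0.0085 by plate), although Ifi27l2a was at -1.62. The list had the opposite sign in the log2 ratio of mean FPKM (-0.065) and in the common range of detected genes (-0.063). Adjusted for detected genes per cell, the medians were -0.46 for immediate early, -0.41 for oxidative phosphorylation, -0.36 for proliferation, -0.23 for NF-kB and 0.31 for interferon genes. Cytosolic ribosome genes had a median of -0.0060 over all cells, with 12 members higher and 12 lower, but plate medians of 0.043, 0.21 and 0.17. Of the genes named here, Stmn1, Icam1 and Zfp36 overlap other gene models and Pcna has processed copies, so their values are uncertain.

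The remaining lists had medians between -0.40 and 0.022 in this contrast. They were -0.40 for phagocytosis and lysosome, -0.33 for TGF-beta signalling, -0.31 for glycolysis, -0.29 for both homeostatic microglia and actin genes, -0.20 for disease-associated microglia, -0.17 for cytokines and chemokines, -0.088 for lipid handling, -0.033 for antigen presentation and 0.022 for complement. All genes had a median of -0.24, and 72.0% of them were lower at the high than at the low dose. Clec7a, a receptor of activated microglia, was lower at the high than at the low dose, with a difference of -2.15, and the invariant chain Cd74, which overlaps Mir5107, was higher by 1.13.

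Spag7 (1.73), the mitochondrial nucleotide carrier Slc25a4 (1.51), Capzb (1.41), Arhgdib (1.35, with the overlap named above), Ruvbl1 (1.33) and hexokinase 2 (Hk2, 1.27) had the greatest positive differences between the doses. Srsf9 (-2.39), Rab1b (-2.03), Gltp (-2.02), Ndufa8 (-2.02) and Cox7b (-1.96) had the greatest negative ones, with Mir3064 (-2.34), which lies within Ddx5 and is uncertain.

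Gpr84, Tnf and Il1a were found together in the same cell more often than independent detection would give in each group. All 3 were present in 29 PBS cells (63.0%, interval 47.5 to 76.8), against 23.8 under independence, in 20 low-dose cells (42.6%, 28.3 to 57.8) against 12.2, and in 18 high-dose cells (38.3%, 24.5 to 53.6) against 11.7. Tnf and Il1a were together in 34 PBS cells (30.4 under independence), 21 low-dose cells (15.96) and 25 high-dose cells (21.1). Gpr84 and Tnf were together in 30, 21 and 21 cells of the 3 groups, and Gpr84 and Il1a in 33, 27 and 21. Cells with more detected genes hold more of any gene, and these counts were not corrected for that.

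Differences from PBS at the 2 doses were correlated across the 4806 genes with r = 0.56, but both shared the PBS cells. Groups drawn at random without any effect gave r = 0.50, and the covariance was 0.144 against 0.111 in those draws. With the PBS cells split between the doses, r was 0.091, and between doses on different plates it was 0.058 to 0.131. Between plates, the low-dose differences correlated at 0.067 to 0.164 and the high-dose differences at 0.125 to 0.143. Adjusted for detected genes per cell, r with split PBS cells was 0.0385, that between doses on different plates -0.0016 to 0.085, and the covariance above that of the draws 0.0081 in place of 0.0323. Genes are not independent replicates.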

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

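Results were recomputed under other settings, giving 4049 values. The tests chosen after seeing the data were thinning to 300000 reads, adjustment for detected genes, subtraction of the median of all genes, leaving out the chromosome 1 copy of mitochondrial DNA and the 3 exclusions of cells in doubt. Of the values, 3450 lay within the spread of the reported ones, 498 moved further and 101 reversed, where a reversal is a change of sign of a result that had the same sign on all 3 plates. Another 98 values changed sign where the plates had differed in sign already, which makes 199 changes of sign in all. The 4 settings with the most reversals were cells with at least 2000 detected genes (27), the ratio of mean FPKM (20), the common range of detected genes (16) and adjustment for detected genes (15). For the reversals and shifts below the cause was not tested. The planned limit of 10% mitochondrial FPKM was not run, because genes of the mitochondrial chromosome were not analysed here. The filter to clusters called microglia-like removed no cell and says nothing about stability, and a Leiden resolution of 1.0 gave 6 clusters in place of 3, which again held 100% of the cells. No paired analysis was possible because a paired test needs replicates and each group was 1 sample. All groups shared the 3 plates, so they were compared within plates, and the mean of these differences is among the settings. Depth limits the shares, since a gene missing from a library is not shown to be absent from the cell. Shares at an FPKM of 1 or more also depend on depth because fewer reads reach that value in a library with fewer reads.

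With at least 2000 detected genes per cell, low-dose differences from PBS were 0.22 for Gpr84, 0.058 for Tnf and 0.59 for Il1a, with a mean of 0.29, all opposite to the reported ones. Low-dose list medians were 0.075 for cytokines and chemokines, 0.10 for phagocytosis, 0.20 for both oxidative phosphorylation and lipid handling, and 0.058 for the ribosome. Nfkbia was 0.40, Itgb2 0.055 and Rps24 0.025, and shares of cells differed by 8.65 points for Gpr84, -6.58 for Tnf and -7.33 for Il1a. High-dose cells under this filter gave -0.72 for Tnf and -0.85 for the mean of the 3 title genes. Their list medians were 0.045 for disease-associated microglia, 0.20 for interferon, 0.17 for antigen presentation, 0.063 for glycolysis, 0.15 for lipid handling and 0.27 for the ribosome. Fcrls was 0.068, Lpl 0.045, Rps3 0.19 and Rpl23 0.055. Between the doses, Il1a was -1.37, the title mean -1.13, disease-associated microglia 0.075, glycolysis 0.031, the ribosome 0.073, Lpl 0.095 and Rpl23 0.34, with shares differing by -23.6 points for Gpr84, -5.77 for Tnf and -9.07 for Il1a.

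Within the common range of detected genes, where the medians of detected genes still differed (2615 in PBS, 2896 in low-dose and 2393 in high-dose cells), low-dose differences were 1.52 for Gpr84, 0.97 for Tnf and 0.86 for Il1a, with a mean of 1.12, and the share with Gpr84 differed by 14.3 points. Low-dose lists gave 0.38 for cytokines, 0.14 for actin genes, 0.24 for interferon, 0.76 for phagocytosis, 0.46 for oxidative phosphorylation, 0.35 for lipid handling and 0.45 for the ribosome. Nfkbia was 0.95 and Itgb2 0.42. High-dose values in this range were -0.33 for Tnf, -0.86 for the title mean, 0.28 for disease-associated microglia, 0.085 for interferon, 0.053 for glycolysis and 0.28 for the ribosome. Between the doses, Gpr84 was -2.65, Tnf -1.31, Il1a -1.98 and their mean -1.98, and the share with Gpr84 differed by -26.4 points.

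Adjusted for detected genes per cell, low-dose differences were 0.21 for Gpr84, -0.15 for Tnf, 0.059 for Il1a and 0.039 for their mean. Low-dose lists gave -0.062 for cytokines, 0.19 for phagocytosis, 0.20 for lipid handling and 0.079 for the ribosome. High-dose differences were -0.48 for Gpr84, -0.016 for Tnf, 0.015 for Il1a and -0.16 for their mean, with Fcrls at 0.042. High-dose lists gave -0.036 for cytokines, 0.23 for homeostatic microglia, 0.15 for disease-associated microglia, 0.11 for interferon, 0.090 for glycolysis, 0.15 for lipid handling and 0.17 for the ribosome. Between the doses the title mean was -0.20, cytokines 0.017 and the ribosome 0.10.

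Relative to the median of all genes, the low-dose title mean was -0.56, with -0.26 for cytokines, 0.11 for lipid handling and 0.034 for the ribosome. The high-dose title mean was -1.02, with 0.20 for disease-associated microglia, 0.076 for interferon, 0.092 for glycolysis, 0.23 for lipid handling and 0.13 for the ribosome. Between the doses the title mean was -0.47, cytokines 0.078, disease-associated microglia 0.043 and the ribosome 0.24.

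In the log2 ratio of mean FPKM, Il1a at the low dose was -0.17 and the title mean -0.18. Low-dose lists gave 0.23 for cytokines, 0.59 for interferon, 0.19 for antigen presentation, 0.21 for phagocytosis, 0.090 for oxidative phosphorylation and 0.39 for lipid handling, with Ifitm3 at 0.40, Tpm4 at 0.29 and Apoe at 0.39. At the high dose Gpr84 was -0.48 and the title mean -1.04. High-dose lists gave 0.047 for homeostatic microglia, 0.14 for disease-associated microglia, 0.38 for interferon, 0.24 for lipid handling and 0.12 for the ribosome, with Txn1 at 0.13, Ifi27l2a at 0.73 and Apoe at 0.056. Between the doses Tnf was -1.20, the ribosome 0.14, Ccl2 -0.85 and Ifi27l2a 0.061.

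Detection at any FPKM above 0 gave differences in share at the low dose of -6.34 points for Gpr84, -14.7 for Tnf and -10.5 for Il1a, at the high dose of -2.08, 2.31 and -4.16, and between the doses of 4.26, 17.02 and 6.38. Detection at an FPKM of 10 or more gave -7.54, -11.6 and -11.7 at the low dose, -24.6, -20.1 and -16.0 at the high dose, and -17.02, -8.51 and -4.26 between the doses.

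A pseudocount of 0.1 gave a low-dose title mean of -1.12, cytokines at -0.71 and, between the doses, ribosome genes at 0.045. Scaling by the median of ratios gave 0.041 for disease-associated microglia and 0.33 for the ribosome between the doses. Without cells rich in rod markers the low-dose title mean was -0.42, the mean between the doses -1.04 and Prph2 at the high dose -0.065. Leaving out the chromosome 1 copy of mitochondrial DNA gave a low-dose title mean of -0.88 and, between the doses, 0.020 for the ribosome. Ribosome genes between the doses were also at 0.10 after thinning and 0.068 without cells rich in S100a8 and S100a9. Low-dose cytokines were -0.25 with all cells, -0.23 with all list members and -0.73 with members in at least 25% of cells. The agreement of the doses with split PBS cells was 0.142 in place of 0.091 for genes in at least 50% of the cells of a group, and 0.0385 after adjustment for detected genes.

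Leaving out each plate in turn kept the sign of every mean difference of Gpr84, Tnf and Il1a, but the share of cells with Gpr84 at the low dose differed by 4.09 points, in place of a negative value, without plate 2. Of the 149 differences of named genes, those of Cxcl16 (0.11) and C1qc (0.047) between the doses changed sign, both without plate 1. Many of the named genes were picked for having the same sign on all 3 plates, and the others for large differences in their lists. Leaving out 1 plate could therefore hardly change their signs, and this count is no check of stability. Over these settings the low-dose cytokine median ranged from -0.49 to -0.18, the value nearest 0 coming without plate 3, and the low-dose lipid median from -0.088 to 0.021, above 0 without plate 1. The ribosome median between the doses ranged from 0.018 to 0.122, above 0 without any of the plates, whereas the pooled median was -0.0060, so the pooled value does not settle its sign. Low-dose lists of NF-kB (0.25), complement (0.19) and disease-associated genes (0.022) were above 0 without plate 1 and glycolysis (0.10) without plate 3, and complement genes between the doses were below 0 without plate 1 (-0.17) and without plate 3 (-0.10). Rescaling to the same sum per cell and leaving out the cell unlike all others changed the sign of 1 and 3 values, none of them with the same sign on all plates, and equal weights for plates changed no sign.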

Other observations

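The tests chosen after the results were seen were the counts of cycling cells and of cells rich in S100a8 and S100a9, the test on rods, the test on proliferation genes and the use of the common range of detected genes beside the adjusted title genes, while adjustment for detected genes, thinning and exclusion of rod-rich cells were chosen after seeing the data but before their results.

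Cells with a mitotic programme were found mainly among PBS cells. At least 3 of 12 mitotic genes had an FPKM of 10 or more in 9 of 46 PBS cells (19.6%, exact interval 9.36 to 33.9), in 1 of 47 low-dose cells (2.13%, 0.054 to 11.3) and in 0 of 47 high-dose cells, which allows a share of up to 7.55%. The PBS cells were spread over all 3 plates, with 3, 4 and 2 cells. Among cells with at least 2000 detected genes the numbers were 9 of 38, 1 of 28 and 0 of 26. No animal was named, and a single litter, eye or mouse with dividing microglia was not excluded.

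A cell in each group was rich in the neutrophil genes S100a8 and S100a9, which encode calprotectin. Their FPKM values were 37099 and 42014 in a PBS cell, 54673 and 63970 in a low-dose cell and 54950 and 6318 in a high-dose cell. Retnlg, another neutrophil gene, was at 1880, 6204 and 16750 in these cells. A low-dose cell of plate 3 differed from all others, with a median correlation of 0.125 with other cells against 0.300 for the next lowest. It held 7293 detected genes.

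The first pattern is the lower level of Gpr84, Tnf and Il1a in dosed cells, set beside the smaller number of detected genes. At the high dose the tables argue against cells with 3 or more rod markers as the cause. Without them the mean difference was -1.45, with -1.88, -0.90 and -1.63 by plate. At the low dose the same exclusion gave -0.42 in place of -0.73 and leaves part of the difference open to such cells. The exclusion also took out 6 PBS cells whose summed rod FPKM was below 100, so it does not isolate rod RNA at either dose. At the low dose, adjustment for detected genes brought the mean difference to 0.039, close to the 0.052 of all genes, in line with fewer detected genes as a candidate explanation. The high-dose value adjusted the same way was -0.16, inside the bound set beforehand for that explanation, but the log2 ratio of mean FPKM was -1.04 and the common range gave -0.86, a weak check since high-dose cells still held fewer genes there (median 2393 against 2615) and low-dose cells, with 1.12, more (2896), so a lower level of these genes and fewer detected genes cannot be told apart at the high dose. Fewer reads do not account for the fewer genes, because at equal reads the high-dose median stayed lower on each plate, by -356 genes at the smallest gap, and less RNA per cell, age, well position and the dose itself remain open.

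The second pattern is the lower level of proliferation genes at the high dose. Adjusted for detected genes per cell, their median difference was -0.75, with -0.99, -0.42 and -0.75 by plate, against -0.053 for all genes, which argues against fewer detected genes as the whole cause. The dose, age and well block differed together, the mice were not named, and none of these was tested as a cause.

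The third pattern is the rod RNA in high-dose cells, where 8 of the 10 markers were in a larger share of cells than in PBS cells. A common pool of free rod RNA would spread evenly, but 3 cells held 71.0% of the rod FPKM of the high-dose group, with 15487 in the highest cell and 1.04 in the median cell. An earlier form of this test, which counted the markers not in a larger share, decided nothing and was replaced after its result was seen. Rods sorted with or in place of microglia, engulfed rod material, rod fragments attached to single microglia and a local effect of neighbouring wells remain open.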
